A study of Mus musculus with 6 samples.

How the data were processed

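The series holds 6 samples of cultured CD63+ mouse liver cells, 3 labelled as DDC injury and 3 as no injury, each hybridised to 1 Agilent array of design 026655 labelled with Cy3. Per the file headers, the spots were quantified with Feature Extraction 11.0.1.1, and the columns used here are in units of intensity: the processed signal, which is background-subtracted and detrended per array, and the median raw signal of the spot and of its local background. The deposited value table holds log2 values of the same 6 arrays, normalized by the authors so that the 6 columns share their quantiles (column medians 6.921 to 6.927). The submitters' notes name limma without a version. The column from which the authors' values started is not stated. Across spots, Spearman's rho was 0.996 to 0.999 with the median raw signal and 0.991 to 0.995 with the processed signal, and spots are not independent replicates. The labels say that VEGF and bFGF were added to the medium of some cultures under names that match no sample title, so this treatment could not be assigned to samples. The names of 2 no-injury files carry numbers of these cultures, so the treatment may be confounded with the no-injury group.

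Probes were named through their transcript accession in a RefSeq table of assembly GRCm38.p6, while the arrays' own annotation is of build mm9, so no coordinates are given. Of 39429 probes that were not controls, 27234 had 1 gene symbol, 0 had several, and 12195 had none in this table and stay unnamed here. The named probes covered 20659 genes, 5476 of them with more than 1 probe. Spots marked as non-uniform or as population outliers were left out, saturated spots were to be kept, and repeated spots of 1 probe were averaged. Signals were taken as log2 of the processed signal minus the array's 75th percentile. A gene was represented by the probe with the highest mean over the 6 arrays, and was tested if this probe was well above background on at least 3 of 6 arrays and had at least 2 values per group. In 55 called genes, of 3986 with at least 2 tested probes, the probes were called in both directions. Genes named in the text whose other probes did not pass are Tenm4, Evc, Vcan, Zeb2, Itgam, Igf1, Atf4 and Ppara.

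The plan was to count the 6 arrays as 6 samples. The series' design text speaks of 6 cell lines. No-injury replicates 1 and 3 agreed within the noise of repeated spots on the arrays themselves, so they were averaged and counted as 1 sample, and the comparison is of 3 DDC injury samples against 2 no-injury samples. Fits with all 6 arrays counted separately, and with the 3 no-injury arrays averaged into 1 sample, were added after this agreement was seen. The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided, prior degrees of freedom 1.35), with adjusted p after Benjamini-Hochberg over all genes tested and a threshold of 0.05. Differences are DDC injury minus no injury on the log2 scale, given with the standard error of the fit. The precision is limited by the number of independent samples, which may be smaller than the number of arrays.

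Before the data were examined, 44 gene lists with 1305 genes were fixed, 113 of the genes in more than 1 list. Lists with at least 5 tested genes were tested with camera at a preset inter-gene correlation of 0.01, adjusted over the lists, and 196 genes with a missing value were left out of these tests. By this test 7 lists were called higher and 7 lower. With an estimated correlation none was called, while 2 had an unadjusted p under 0.05, and fry called 24. Fry tests whether the genes of a list move 1 way on balance and makes no comparison with other genes.

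The named genes followed a rule fixed before the data were examined. It takes the 12 largest differences each way past the threshold among genes well above background on all 6 arrays whose groups did not overlap. Clone names, predicted genes, number-only loci and saturated probes are left out of this ranking. It adds up to 5 genes each way that were not well above background on any array of the lower group, up to 4 genes with the smallest adjusted p from each list, and a fixed set of marker genes. A few of the genes it takes are not reported here. Of that set, Cd68 and H19 had no probe named here, Xist, Ddx3y and Fgf2 were not well above background on any array, and Eif2s3y was so on 1 DDC injury array. Folds of genes not well above background in a whole group are bounds: the brighter group's mean against the dimmer group's mean of, per array, the higher of the lowest signal among probes well above background and the probe's own signal. Such bounds were computed for 67 genes higher and 136 genes lower.

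The fit was tested on simulated data: in 5 runs with 15430 genes, of which 200 were shifted, 75.4% of 8-fold and 5.4% of 2-fold shifts were recovered, and 3.4 genes without a shift were called per run. A shifted list was called in 5 of 5 runs and no other list in any. The simulated noise was independent between genes and had the same spread in both groups. In the data, estimated correlations within lists reached 0.71. The runs therefore cannot show how often lists of correlated genes, or genes with unequal spreads, are called wrongly.

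Alternatives fixed before the data were examined covered the background correction (normexp with an offset of 50, run on the median signal since the files hold no mean signal), quantile and median normalization, the authors' values, the filter on dim probes, outlier spots, the choice of probe, an intensity trend, array weights, the replicate number and the scan as blocks, thresholds, list tests and leaving out each replicate. DDC injury replicate 1 was scanned on day 1 and the other arrays on day 2, in scan 2 (DDC injury replicates 2 and 3) and scan 3 (the no-injury arrays). The day was used as a covariate and the scan as a random block. Each scan holds 1 group, so neither separates the scan from the group. The median difference of all tested genes was -0.07, and between -0.05 and 0.07 under the other scalings, the largest value being that with normexp and the 75th percentile.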

Results

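Gene expression was measured on 6 arrays of 1 colour, the Agilent whole-mouse-genome design, each hybridised with RNA from cultured mouse liver cells that had been sorted for CD63, a tetraspanin of late endosomes and exosomes. The 3 arrays of the DDC injury group held cells from livers injured with DDC, a porphyrinogenic compound usually given in the diet that blocks haem synthesis and causes cholestatic injury. The 3 arrays of the no-injury group held cells from uninjured livers. Sorted cells of both groups had been grown in a medium with serum, HGF, EGF, insulin and dexamethasone, so the values describe cultures and not freshly isolated cells. VEGF and bFGF had been added to some cultures that the labels name by numbers and do not tie to a sample. The names of 2 no-injury files carry such numbers, so the treatment could lie within the no-injury group. The series is concerned with quiescent stem cells of the adult liver and their descendants, and the labels give 1 comparison, injured against uninjured livers. Each array held 43020 spots that were not controls. The 75th percentile of the processed signal lay between 1441 and 2271 intensity units, and between 65.0% and 74.8% of the spots were well above background. No spot was saturated, and the number of independent samples limits the precision.

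The 3 no-injury arrays lay very close to each other. Over 137 bright probes printed 10 times, no-injury replicates 1 and 3 did not differ beyond the sampling noise of repeated spots (chi-square 150.5, 136 degrees of freedom, p = 0.187), and they were therefore averaged and counted as 1 sample. The same chi-square test over 137 probes gave p = 3.33e-10 between replicates 1 and 2 and p = 4.87e-32 between replicates 2 and 3. The spread of the difference between DDC injury arrays was 3 to 7.2 times that of repeated spots, against 1 to 1.69 times between no-injury arrays. It was 3 times between DDC injury replicates 1 and 3, 7.01 between 1 and 2 and 7.2 between 2 and 3. Over the tested genes, dim ones included, replicates 2 and 3 correlated more closely (Pearson r = 0.987) than 1 and 3 (0.97). Over 6256 bright genes the spread of the log2 difference was smallest between replicates 1 and 3, at 0.14. It was 0.269 between 2 and 3 and 0.326 between 1 and 2. Whether any DDC injury arrays share an origin was not tested. The chi-square test counts no labelling noise, so it cannot show that no-injury replicate 2 is a separate culture. Replicate 2 was counted as a sample of its own, and the comparison below is of 3 DDC injury samples against 2 no-injury samples. DDC injury replicate 1 was scanned on a day of its own, and the other 5 arrays on a second day. Each of the 3 scans held arrays of 1 group only, so the scan is confounded with the group.

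Of 15626 genes tested, 2761 were higher and 2464 lower in the DDC injury group, and 10401 did not pass the test. Of those that passed, 1343 were at least 2-fold higher and 1344 at least 2-fold lower. The fit shares 1 estimate of the spread between the groups, although the no-injury samples lay closer together. For C2 the SD was 0.002 over the 2 no-injury samples and 1.114 over the 3 DDC injury samples. Standard errors and adjusted p are therefore too small if the 2 no-injury samples are not separate cultures. Clone names and predicted genes were left out of the ranking by difference. Among the other genes well above background on all 6 arrays, the largest rise was that of Igf2bp3, an oncofetal RNA-binding protein. It rose by 7.21 ± 0.14 on the log2 scale (SE, 3 and 2 samples, 148-fold, adjusted p = 0.000587). Srgap3 rose by 7.11 ± 0.12 (138-fold) and Foxd1, a forkhead transcription factor, by 7.10 ± 0.18 (137-fold), each with the same adjusted p of 0.000587. The next genes were the teneurin Tenm4 (5.98), Glrp1 (5.83), the glypican Gpc1 (5.79), the prolactin-family gene Prl2c1 (5.74), the kinase Lrrk2 (5.69), the phosphatase Ptpn22 (5.67), Rgs17 (5.19), Enpp2, which encodes autotaxin (5.03), and Gas1 (4.85), with adjusted p between 0.000587 and 0.00184. The order depends on the background correction. With normexp and the 75th percentile Igf2bp3 rose by 4.96, Foxd1 by 5.46 and Prl2c1 by 5.75, and in the authors' values Igf2bp3 rose by 5.58 and Foxd1 by 5.97. A second probe of Tenm4 differed by 0.75 and did not pass. The probes of Srgap3 ranged from 3.40 to 7.11, and the mean of its probes rose by 4.68.

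Among genes well above background on all 6 arrays and ranked in the same way, the largest fall was that of Pdzk1ip1, a membrane protein of epithelia. It fell by 8.71 ± 0.38 on the log2 scale (SE, 418-fold lower, adjusted p = 0.000968). Prom1, which encodes the progenitor surface protein CD133, fell by 8.69 ± 0.21 (412-fold lower, adjusted p = 0.000587), from a mean of 1.96 ± 0.18 (SD, n = 2) to -6.73 ± 0.28 (SD, n = 3) relative to the array's 75th percentile. The cytochrome P450 gene Cyp4b1 differed by -8.63, the uroplakin Upk1b by -7.73 and the sulfotransferase Sult1a1 by -7.66. Serinc2 and Gas6, a ligand of the TAM receptor kinases, each differed by -6.32, the acute-phase gene Crp by -6.22, and the complement gene C2 by -5.97. Nme5 differed by -5.88, Rps4l by -5.81 and Misp by -5.43, and adjusted p for these genes lay between 0.000587 and 0.00911. Without DDC injury replicate 1, Cyp4b1 differed by -7.58 and C2 by -5.34, and without replicate 2 Serinc2 differed by -5.67. Another probe of Pdzk1ip1 differed by -6.61 and another of Prom1 by -9.92. The order of the falls depends on the replicates. Without DDC injury replicate 1, Prom1 differed by -8.699 and Pdzk1ip1 by -8.51, and without replicate 2 Cyp4b1 differed by -9.167 and Pdzk1ip1 by -9.045. These falls also depend on the background correction: with normexp and the 75th percentile Prom1 differed by -6.56, Sult1a1 by -7.34, Upk1b by -5.92, Rps4l by -3.93 and Misp by -3.54, and in the authors' values Prom1 differed by -7.33. Genes not well above background on any array of the lower group have only a bound. Cxcl3, a neutrophil chemokine, was at least 103-fold higher in the DDC injury group, Pate14 at least 67.4-fold, Ndst3 at least 42.8-fold, Stac at least 28.6-fold and Il18rap at least 17.7-fold (adjusted p = 0.00149 to 0.0172). Pira2 was at least 335-fold lower, Marveld2, a protein of tricellular tight junctions, at least 182-fold, Evc at least 126-fold, Cyp2j6 at least 108-fold and the protease Mmp7 at least 89.2-fold (adjusted p = 0.000587 to 0.00305). The bounds hold for the processed signal only. With normexp and the 75th percentile the fitted difference was 4.03 for Cxcl3, 3.46 for Pate14 and -5.44 for Pira2, and in the authors' values it was 4.83, 4.33 and -6.58. Without DDC injury replicate 2 the bound for Cxcl3 was 46.9-fold and that for Stac 50.6-fold. Another probe of Pira2 differed by -4.85. Another probe of Evc differed by -1.43 and did not pass.

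**Figure D1:**
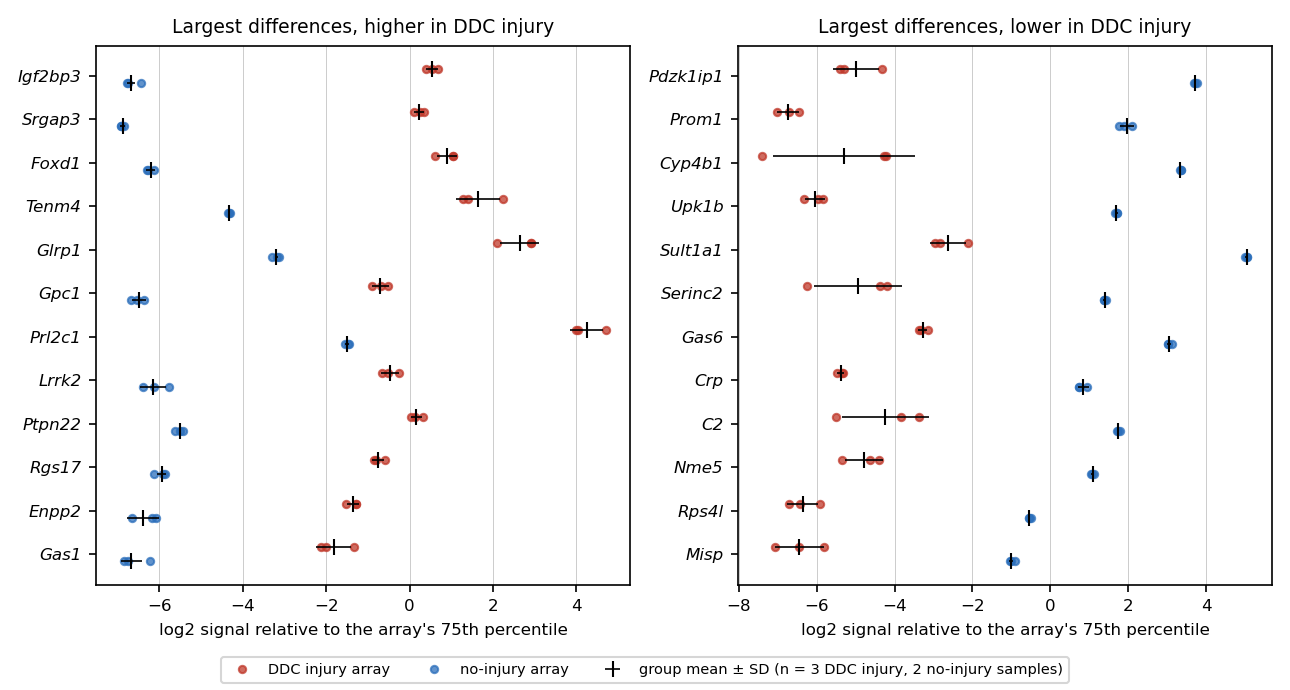
The 12 genes with the largest differences each way under the naming rule are shown. The horizontal axis gives the log2 processed signal of every array relative to its 75th percentile. Dots are arrays, ticks are group means and bars are SD over 3 DDC injury and 2 no-injury samples. All DDC injury arrays lie to the right of the no-injury arrays in the left panel, by 7.21 in the mean for Igf2bp3, and to their left in the right panel, by -8.71 for Pdzk1ip1.

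The counts changed with the way the no-injury arrays were counted. With these 3 arrays averaged into 1 sample, 342 genes were higher and 206 lower, all of them among the genes above, and 112 of the 189 genes past the threshold that the naming rule takes no longer passed, Cyp4b1, Serinc2, C2, Cxcl3 and Stac among them. Without no-injury replicate 2 the counts were 350 and 164, and without DDC injury replicate 3 they were 1727 and 1549. Within the second scan day, which leaves out DDC injury replicate 1 and still sets 1 scan against another, 2793 genes were higher and 2814 lower, and 2400 and 2233 of them were the same genes. With the scan day as a covariate the counts were 2840 and 2801. DDC injury replicate 1 is the only array of its day, so this fit sets it aside too and is no separate check. The filter left 15626 genes in this fit and 15345 in the fit without replicate 1. With the scan as a random block, at an estimated correlation of 0.176, the counts were 2297 and 2025. Genes of chromosomes 15 and X lay above the other chromosomes by 0.45 and 0.46 on the log2 scale in the median.

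Markers of the sorted cells and of liver lineages differed in part. Cd63, by which the cells had been chosen, differed by -0.11 ± 0.17 (SE, adjusted p = 0.659). The biliary keratins Krt19 (0.37, adjusted p = 0.242) and Krt7 (0.16, adjusted p = 0.468), osteopontin Spp1 (-0.25, adjusted p = 0.362), the hepatocyte regulator Hnf4a (-0.09, adjusted p = 0.746), vimentin Vim (0.02, adjusted p = 0.939) and mesothelin Msln (0.15, adjusted p = 0.467) did not pass either, and all of these were well above background on the 6 arrays. The epithelial adhesion gene Epcam fell by 2.58 ± 0.24 (adjusted p = 0.00425) and the progenitor transcription factor Sox9 by 1.57 ± 0.28 (adjusted p = 0.0194). Albumin, Alb, fell by 6.14 ± 0.65 (adjusted p = 0.00575) and was well above background on 2 of the 3 DDC injury arrays, and transthyretin, Ttr, fell by 3.94 ± 0.58 (adjusted p = 0.0118). The fetal hepatocyte gene Afp rose by 2.86 ± 0.26 (adjusted p = 0.00403) and the Wnt-responsive stem-cell gene Lgr5 by 3.35 ± 0.43 (adjusted p = 0.00873). The mesothelial regulator Wt1 fell by 3.30 (adjusted p = 0.0101, well above background on 1 of the 3 DDC injury arrays) and Ly6a, which encodes Sca-1, by 1.25 (adjusted p = 0.0425). Cdkn1a, a cyclin-dependent kinase inhibitor, rose by 1.09 (adjusted p = 0.00602) and Cdkn2a by 0.73 (adjusted p = 0.0216), while Cdkn1c differed by 0.03 (adjusted p = 0.947). With the 3 no-injury arrays averaged, the markers from Epcam to Cdkn2a that passed here no longer did (adjusted p = 0.058 to 0.202), and Ly6a did not pass within the second scan day either (adjusted p = 0.058). Krt19 passed without DDC injury replicate 2 and with array weights, and Spp1 in the authors' values and with normexp and quantile normalization.

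**Figure D2:**
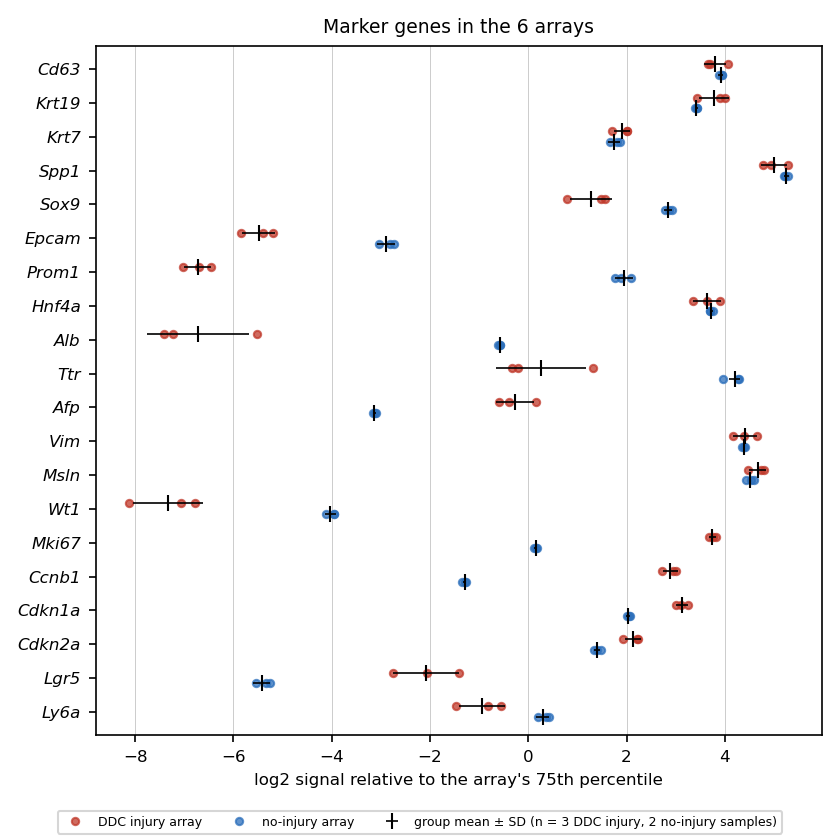
Marker genes fixed before the data were examined, with the log2 processed signal of each array relative to its 75th percentile on the horizontal axis; dots are arrays, ticks are group means and bars are SD over 3 DDC injury and 2 no-injury samples. Cd63, Krt19, Krt7, Hnf4a, Vim and Msln overlap between the groups, whereas Prom1 differs by -8.69, Alb by -6.14 and Mki67 by 3.60.

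Cell division genes rose together. Of 43 tested genes of the G2/M and mitosis list, 41 rose and none fell (42 rose adjusted over the list alone), with a median of 3.58 on the log2 scale, and 38 still rose with the 3 no-injury arrays averaged. The proliferation antigen Mki67 rose by 3.60 ± 0.10 (12.1-fold, adjusted p = 0.000587), the mitotic kinases Aurka by 3.71 and Plk1 by 3.62, the kinesin Kif20a by 3.64 and cyclin B1, Ccnb1, by 4.18. Of 43 genes of G1/S and DNA replication, 28 rose and none fell (29 adjusted over the list alone, median 1.51), among them the replication genes Gins2 (2.57) and Rfc4 (1.79) and the cohesion gene Dscc1 (3.28). Of 21 replication-dependent histone genes, 15 rose and none fell (17 adjusted over the list alone, median 1.07), H3c8 by 3.09, H2ac11 by 3.01 and H2ac15 by 2.08. Against other genes the lists passed camera with adjusted p = 3.68e-27, 3.19e-09 and 8.85e-06, but not with estimated correlations, at adjusted p = 0.161, 0.772 and 0.556. Within the second scan day the medians were 3.51, 1.58 and 1.15. With the 3 no-injury arrays averaged, 4 G1/S genes and 2 histone genes rose.

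Lists of lipid synthesis, protein synthesis and folding, and oxidative phosphorylation were called higher by camera, each with part of its genes past the threshold. Of 31 genes of cholesterol and fatty acid synthesis, 19 rose and none fell (22 adjusted over the list alone), with a median of 1.28 (camera adjusted p = 9.07e-07, adjusted p = 0.772 with an estimated correlation). They included the sterol regulator Srebf2 (1.55 ± 0.11), squalene epoxidase Sqle (1.56) and the desaturase Fads2 (2.05). Of 42 ribosomal protein genes, 11 rose and none fell (8 adjusted over the list alone, median 0.36, camera adjusted p = 7e-05, adjusted p = 0.772 with an estimated correlation), Rpl18 by 0.72 and Rpl3 by 0.58. This call ended under quantile normalization, where the median was 0.12, with normexp and quantile normalization, and in the authors' values, where it was 0.11. Of 30 genes of the unfolded protein and heat shock response, 9 rose and 3 fell (12 and 3 adjusted over the list alone, median 0.47, camera adjusted p = 0.0213, adjusted p = 0.556 with an estimated correlation). Manf (0.87), Creld2 (1.19) and the transcription factor Atf4 (0.69) rose and Herpud1 fell by 0.87, and the call ended under quantile normalization (median 0.34), in the authors' values (median 0.36) and with the mean of a gene's probes (median 0.33). Of 38 genes of oxidative phosphorylation, 3 rose and none fell (1 adjusted over the list alone, median 0.16, camera adjusted p = 0.0189, adjusted p = 0.772 with an estimated correlation), the largest being Cyc1 (1.07), and the call ended under quantile normalization, with normexp under either scaling, in the authors' values (median 0.01), with the mean of a gene's probes, array weights or fry, and without DDC injury replicate 2 or no-injury replicate 2. Within the second scan day the medians of these 4 lists were 1.38, 0.42, 0.47 and 0.21, and 18, 20, 10 and 5 of their genes rose. With the 3 no-injury arrays averaged, 1, 0, 0 and 0 of their genes rose in limma.

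Lists of biliary and hepatocyte identity were called lower, and part of their genes fell. Of 27 cholangiocyte and liver progenitor markers, 13 fell and 1 rose (15 and 1 adjusted over the list alone), with a median of -0.83 (camera adjusted p = 0.000184, adjusted p = 0.556 with an estimated correlation). Besides Prom1, the annexin Anxa13 fell by 1.57 ± 0.10, and Krt23 was at least 9.91-fold lower. Of 29 genes of hepatocyte identity and secreted proteins, 11 fell and 2 rose (13 and 3 adjusted over the list alone), with a median of -1.43, or -1.41 with genes below background at their bound (camera adjusted p = 0.00127, adjusted p = 0.773 with an estimated correlation). Apolipoprotein Apoa1 was at least 42.5-fold lower and the fibrinogen chains Fga and Fgg at least 22.1-fold and 2.9-fold lower, and the call ended when only genes well above background on all 6 arrays were kept (median -1.35). Of 26 genes of cytochrome P450 and drug metabolism, 9 fell and none rose (9 adjusted over the list alone, median -0.87, camera adjusted p = 0.00172, adjusted p = 0.772 with an estimated correlation), the glutathione transferases Gsta3 (-5.35) and Gstm1 (-1.78) among them. Of 28 complement and acute-phase genes, 10 fell and 2 rose (11 and 2 adjusted over the list alone, median -2.00, or -1.96 with genes below background at their bound, camera adjusted p = 0.00756, adjusted p = 0.772 with an estimated correlation), and besides Crp and C2 the complement regulator Cfi was at least 37.4-fold lower and C9 at least 3.82-fold lower. Within the second scan day the medians of these 4 lists were -0.77, -1.15, -0.60 and -1.53. With the 3 no-injury arrays averaged, 3, 3, 2 and 2 of their genes fell.

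Lists of epithelial junction genes, mesothelial markers and antigen presentation genes were also called lower, each with part of its genes past the threshold. Of 37 epithelial junction and keratin genes, 16 fell and 2 rose (16 and 3 adjusted over the list alone), with a median of -0.97 (camera adjusted p = 0.00383, adjusted p = 0.556 with an estimated correlation). The tight-junction protein occludin, Ocln, fell by 3.07 ± 0.10 and the protease inhibitor Spint1 by 3.22 ± 0.23, and the desmocollin Dsc2 was at least 3.43-fold lower. Of 20 mesothelial cell markers, 9 fell and 1 rose (11 and 1 adjusted over the list alone, median -1.06, camera adjusted p = 0.00564, adjusted p = 0.556 with an estimated correlation), among them P-cadherin, Cdh3 (-2.40), and Igfbp5 (-2.71). Of 24 genes of MHC class I and II antigen presentation, 6 fell and none rose (6 adjusted over the list alone, median -0.60, camera adjusted p = 0.0338, adjusted p = 0.773 with an estimated correlation), including Cd1d1 (-0.83) and H2-D1 (-0.99). Within the second scan day the medians of these lists were -0.44, -0.99 and -0.15, and the antigen presentation list no longer passed camera there (adjusted p = 0.135). Its call also ended in the authors' values, with normexp and quantile normalization, the mean of a gene's probes, array weights or fry. With the scan day as a covariate it ended too, a fit that likewise sets DDC injury replicate 1 aside. With the 3 no-injury arrays averaged, 4, 2 and 0 genes of these lists fell in limma.

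**Figure D3:**
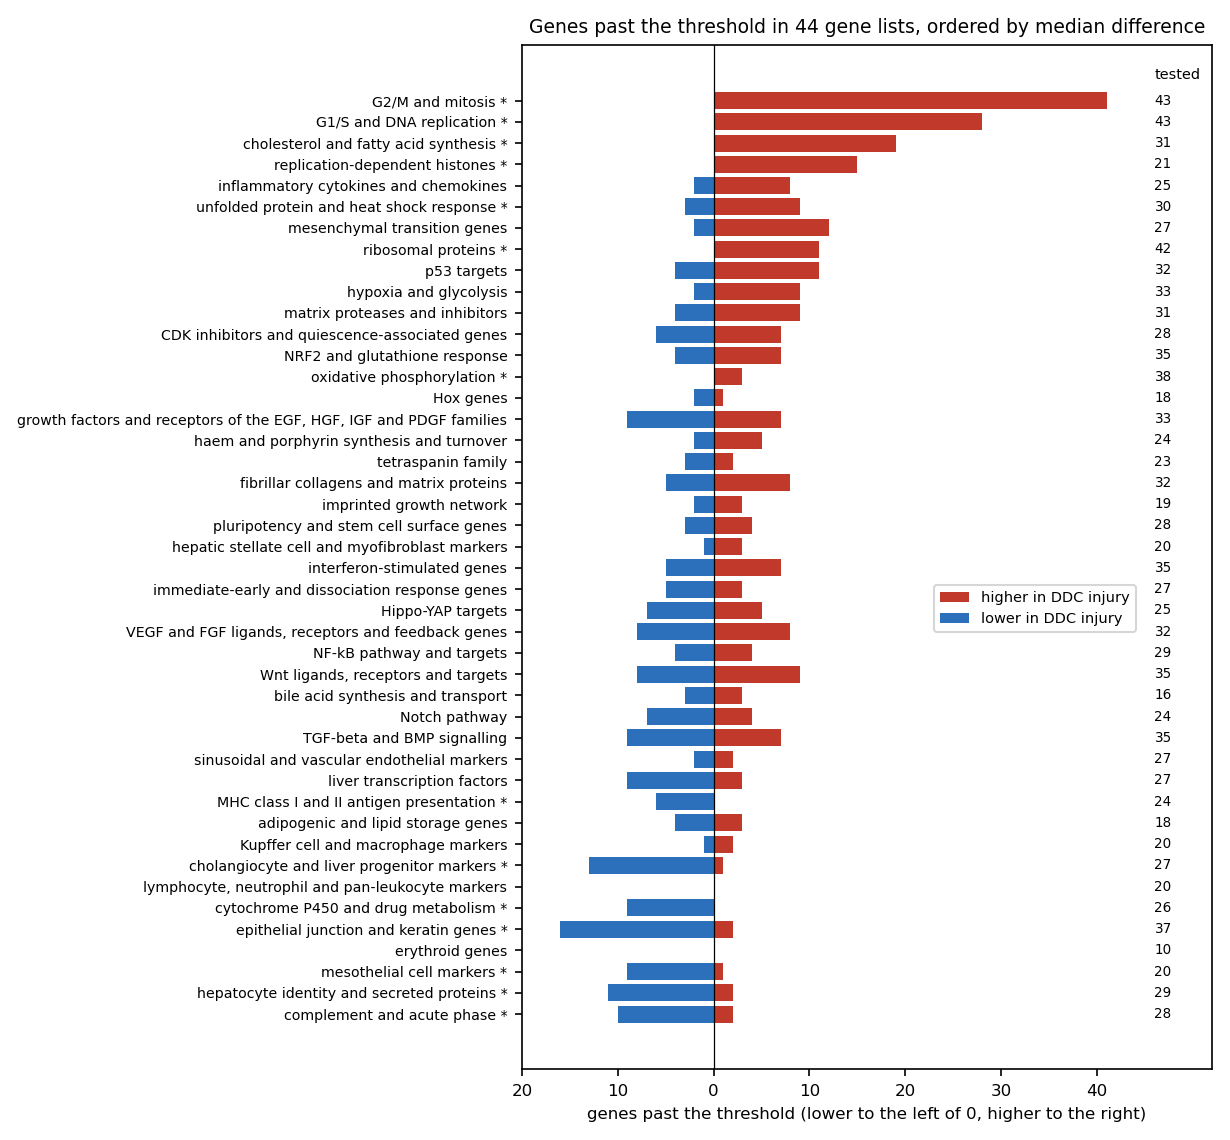
Bars give, for each of 44 gene lists, the number of genes past the threshold that were higher (right of 0) or lower (left of 0) in the DDC injury group; the number tested stands at the right, and a star marks lists that passed camera with a preset correlation. G2/M and mitosis has 41 of 43 genes higher, and epithelial junction and keratin genes have 16 of 37 lower.

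Matrix and mesenchymal genes moved in both directions, and their lists did not pass camera in the comparison of 3 and 2 samples. Of 27 mesenchymal transition genes, 12 rose and 2 fell (12 and 3 adjusted over the list alone, median 0.46, camera adjusted p = 0.0555, and 0.0241 within the second scan day). The transcription factors Twist2 (2.22) and Zeb2 (1.73) rose, and Tgfb3 (-3.56) and Fap (-2.06) fell. The list was also called without DDC injury replicate 2, without the filter on dim probes, with every probe tested and with array weights. It was called as well with the replicate number as a block, without genes shared between lists, and by fry. The call with the scan day as a covariate repeats that within the second scan day, since both set DDC injury replicate 1 aside. Of 32 fibrillar collagens and matrix proteins, 8 rose and 5 fell (10 and 5 adjusted over the list alone, median 0.04, camera adjusted p = 0.686). Col5a1 rose by 5.99, with 1 of the 3 no-injury arrays well above background, Vcan rose by 3.30 with another probe at -0.66, and Col11a1 was at least 8.44-fold lower. Of 31 matrix proteases and inhibitors, 9 rose and 4 fell (10 and 4 adjusted over the list alone, median 0.25, camera adjusted p = 0.146, with a call when the scan day was a covariate and by fry), among them the inhibitor Timp1 (2.46) and the gelatinase Mmp2, which was at least 4.58-fold higher. Of 20 hepatic stellate cell and myofibroblast markers, 3 rose and 1 fell (2 and 1 adjusted over the list alone, median 0.01, mean -0.19, camera adjusted p = 0.949), and Acta2 (-1.90, adjusted p = 0.452), Col1a1 (1.04, adjusted p = 0.182) and Pdgfrb (0.10, adjusted p = 0.966) did not pass. These values depend on DDC injury replicate 1: within the second scan day Col1a1 (1.47, adjusted p = 0.0146) and Pdgfrb (1.47, adjusted p = 0.0342) passed, and Acta2 differed by -0.37.

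Markers of other liver cell types did not pass as lists. Of 27 endothelial markers, 2 rose and 2 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.766), with Stab1 higher (3.24) and Flt1 lower (-1.37). Of 20 Kupffer cell and macrophage markers, 2 rose and 1 fell (2 and 1 adjusted over the list alone, camera adjusted p = 0.845), among them Mrc1 (3.54), Fcgr3 (1.52) and Itgam (-2.73, with other probes that did not pass). Of 20 leukocyte markers and 10 erythroid genes, none passed in limma (0 adjusted over the list alone, 2 and 0 at an unadjusted p under 0.05). Within the second scan day 1 leukocyte marker, S100a8, rose (1.40, adjusted p = 0.0172) and 1, Cd4, fell (-1.10, adjusted p = 0.0108). These lists did not pass camera (adjusted p = 0.428 and 0.541) or fry (adjusted p = 0.609 and 0.563). Pecam1 (-0.79, adjusted p = 0.193), Kdr (-0.83, adjusted p = 0.178), Ptprc (0.36, adjusted p = 0.787) and Adgre1 (0.01, adjusted p = 0.996) did not pass, though Pecam1 did without DDC injury replicate 3 and Kdr with normexp and quantile normalization. The endothelial, macrophage, leukocyte and erythroid lists moved with DDC injury replicate 1. Their medians were -0.42, -0.69, -0.84 (-0.57 with genes below background at their bound) and -1.02 over all samples, and 0.21, 0.26, -0.01 and -0.16 within the second scan day.

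Signalling and stress lists held genes that moved both ways. Of 25 inflammatory cytokines and chemokines, 8 rose and 2 fell (8 and 2 adjusted over the list alone, median 0.63, camera adjusted p = 0.055, and 0.0377 within the second scan day), with Csf2 (3.54), Ccl5 (3.51) and Ccl9 (4.55) higher and Cx3cl1 lower (-1.12). This list was also called under quantile normalization, without the filter on dim probes, with the mean of a gene's probes and with every probe tested. Array weights, the replicate number as a block, fry, and leaving out DDC injury replicate 2 or no-injury replicate 3 gave a call as well. So did the scan day as a covariate, which sets DDC injury replicate 1 aside as the second scan day does. Of 29 genes of the NF-kB pathway, 4 rose and 4 fell (4 and 4 adjusted over the list alone, camera adjusted p = 0.6), with Ptgs2 higher (3.25) and Birc2 lower (-2.09). Of 35 interferon-stimulated genes, 7 rose and 5 fell (7 and 5 adjusted over the list alone, camera adjusted p = 0.901), with a median of -0.07 and a mean of -0.06 while the test's direction was up. Of 35 genes of TGF-beta and BMP signalling, 7 rose and 9 fell (7 and 11 adjusted over the list alone, median -0.39, camera adjusted p = 0.268, called lower by fry at adjusted p = 0.0105), and Fstl3, an activin antagonist, fell by 4.67 ± 0.12. Of 32 VEGF and FGF ligands, receptors and feedback genes, 8 rose and 8 fell (10 and 8 adjusted over the list alone, camera adjusted p = 0.949). Vegfd (4.79) and Etv4 (3.25) rose, Fgfr3 (-4.29) and Fgf18 (-2.45) fell, and Vegfa differed by 0.57 (adjusted p = 0.541), but passed without DDC injury replicate 2 and with array weights. Of 24 Notch pathway genes, 4 rose and 7 fell (4 and 8 adjusted over the list alone, camera adjusted p = 0.766), with the receptor Notch3 (2.80) and the feedback gene Nrarp (2.12) higher. Of 35 Wnt ligands, receptors and targets, 9 rose and 8 fell (10 and 9 adjusted over the list alone, camera adjusted p = 0.901), with Wnt7b higher (2.92) and the ubiquitin ligase gene Rnf43 lower (-2.53).

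Of 33 hypoxia and glycolysis genes, 9 rose and 2 fell (9 and 2 adjusted over the list alone, median 0.26, camera adjusted p = 0.0616), with hexokinase Hk2 (2.58) and pyruvate kinase Pkm (1.5) higher, and the list was called without DDC injury replicate 2, without the filter on dim probes, with the mean of a gene's probes, every probe tested or the replicate number as a block, and by fry. Of 32 p53 targets, 11 rose and 4 fell (11 and 4 adjusted over the list alone, median 0.27, camera adjusted p = 0.13), Aen by 1.06 and Phlda3 by 1.03. Of 28 cyclin-dependent kinase inhibitors and quiescence-associated genes, 7 rose and 6 fell (7 and 6 adjusted over the list alone, median 0.19, camera adjusted p = 0.845, called lower by fry at adjusted p = 0.0195), Gas1 and Rbl1 (1.67) rising and Gas6 and Rbl2 (-1.01) falling. Of 27 liver transcription factors, 3 rose and 9 fell (5 and 10 adjusted over the list alone, median -0.59, camera adjusted p = 0.13), Ppara (-2.09) among those that fell. Of 24 genes of haem and porphyrin synthesis and turnover, the pathway that DDC disturbs, 5 rose and 2 fell (4 and 2 adjusted over the list alone, median 0.08, camera adjusted p = 0.541, called higher by fry at adjusted p = 0.00845). Uros fell by 0.77, and ferrochelatase Fech (-0.25, adjusted p = 0.106), Alas1 (0.07, adjusted p = 0.838) and Hmox1 (0.34, adjusted p = 0.661) did not pass, though Hmox1 did without DDC injury replicate 2 and Fech under that and other settings. Of 35 NRF2 and glutathione response genes, 7 rose and 4 fell (6 and 4 adjusted over the list alone, median 0.17, mean -0.05, camera adjusted p = 0.75), and Nqo1 differed by 1.5 (adjusted p = 0.0529) and passed under several other settings, quantile normalization and array weights among them. The p53 list was called with every probe tested and that of liver transcription factors without the filter on dim probes, and fry called both.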

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

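No test in this part was chosen after the result was seen. Of 7008 tested probes with no gene name in the table used here, which the comparison of named genes leaves out, 751 were higher in the DDC injury group and 817 lower. No explanation was weighed for this.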

How the results depend on the processing

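The fits with all 6 arrays counted separately and with the no-injury arrays averaged were chosen after the agreement of these arrays was seen. The number of genes higher (2761) and lower (2464) moved by over 1.5 times to 342 and 206 with the no-injury arrays averaged. It moved to 1127 and 904 at adjusted p under 0.01 and to 1343 and 1344 at 2-fold or more, as follows from stricter limits. Leaving out DDC injury replicate 1 also removes a sample and gave 2793 and 2814 genes. Leaving out DDC injury replicate 2 gave 3693 and 3146, and leaving out DDC injury replicate 3 gave 1727 and 1549. These 3 fits keep 2 no-injury samples, whereas averaging leaves 1. They therefore cannot show whether fewer samples account for the fall with averaging. Why averaging the no-injury arrays lowered the counts was not tested. The counts moved to 4398 and 4177 with array weights and to 4243 and 3789 with every probe tested, where more values are tested. Leaving out each replicate in turn gave 350 to 3693 genes higher, 164 to 3146 lower and 14 to 16 lists called, lowest without no-injury replicate 2 and, next, without DDC injury replicate 3 (1727 and 1549). Where a group was left with 1 sample, it was assumed to vary like the other group. Under every other setting run, the gene counts stayed within 1.5 times. The number of lists called was 14, and 0 with an estimated correlation (2 at an unadjusted p under 0.05) and 24 with fry, whose tests differ in what they compare. The list of cyclin-dependent kinase inhibitors and quiescence-associated genes, with a median of 0.187, was called lower by fry and had no call by camera, where its direction was up; the cause was not tested, nor were those of the shifts with array weights and left-out replicates. Of 189 named genes past the threshold, 73 stayed past it in every fit with other values or another model, and 0 reversed. Leaving aside the fits with the no-injury arrays averaged gave 75. This small change does not show that the number of no-injury samples matters little. Leaving out no-injury replicate 2 also leaves 1 such sample. With the replicate number as a block, in a fit of 6 arrays, 2839 genes were higher and 2726 lower. Correlations of samples with the same number across the groups were 0.117, 0.018 and 0.121, so the numbers were not taken as pairs. Leaving out genes with a saturated spot gave no value, since no spot was saturated. Between 65.0% and 74.8% of the spots were well above background, which limits folds of dimmer genes to bounds.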

Other observations

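The tests for a few strongly changed genes, for brain RNA and for both explanations of the close no-injury arrays were chosen after the values were seen, as were the single genes named for lung, haemoglobin and brain. Several remaining gene groups moved in both directions without passing camera, while fry called those of growth factors, immediate-early genes and Hippo-YAP targets lower (adjusted p = 0.0179, 0.0196 and 0.0418). Of 33 growth factors and receptors of the EGF, HGF, IGF and PDGF families, 7 rose and 9 fell (9 and 9 adjusted over the list alone, median 0.10, mean -0.30, adjusted p = 0.949), with Igf1 higher (2.17) and Pdgfd (-4.87) and stem cell factor Kitl (-1.47) lower. Of 18 adipogenic and lipid storage genes, 3 rose and 4 fell (3 and 4 adjusted over the list alone, median -0.65, adjusted p = 0.599), Angptl4 (2.37) and Fabp5 (2.11) being higher and Gpd1 (-3.05) lower. Of 27 immediate-early and dissociation response genes, 3 rose and 5 fell (3 and 5 adjusted over the list alone, median -0.07, adjusted p = 0.476), with Fosl1 at 3.17, Jun at -1.97 and Rhob at -0.89. Of 25 Hippo-YAP targets, 5 rose and 7 fell (8 and 9 adjusted over the list alone, median -0.07, mean 0.08, adjusted p = 0.766), Birc5 at 3.58 and Ankrd1 at -0.98. Of 16 genes of bile acid synthesis and transport, 3 rose and 3 fell (3 and 3 adjusted over the list alone, median -0.32, adjusted p = 0.76), among them the transporters Abcb1b (1.5) and Abcb4 (1.16).

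Developmental lists were also mixed. Of 28 pluripotency and stem cell surface genes, 4 rose and 3 fell (3 and 2 adjusted over the list alone, median 0.02, mean -0.10, adjusted p = 0.949), and Sox2 was at least 5.67-fold higher. Of 19 genes of the imprinted growth network, 3 rose and 2 fell (3 and 2 adjusted over the list alone, median 0.03, adjusted p = 0.949), with Mest higher (3.17), Ndn lower (-2.58) and Peg3 at least 6.54-fold lower, while Igf2 (-0.04, adjusted p = 0.955) and Dlk1 (-0.16, adjusted p = 0.917) did not pass. Of 18 Hox genes, 1 rose and 2 fell (1 and 2 adjusted over the list alone, median 0.13, mean -0.16, adjusted p = 0.766), and Hoxc9 and Hoxa3 were at least 2.18-fold and 2.58-fold lower. Of 23 tetraspanin genes, the family of Cd63, 2 rose and 3 fell (2 and 2 adjusted over the list alone, median 0.05, mean -0.36, adjusted p = 0.949), and Tspan15 was among the lower genes (-1.59).

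Some genes abundant in lung were measured on the 5 arrays of the second scan day and lay far lower on DDC injury replicate 1. Sftpc, surfactant protein C, was at -9.53 there and between -0.17 and 1.22 on the others, and Sftpb at -8.72 against -2.27 to -1.98. The haemoglobin genes Hbb-bt (-9.23 against -1.84 to -1.24) and Hba-a1 (-5.51 against -0.78 to 1.62) were also lower on replicate 1. Over 21 other lung genes from a list written before the test, 1 of them in another tissue's list and 1 in a liver list, DDC injury replicates 2 and 3 lay above replicate 1 by 1.44 ± 0.52 (SE, bootstrap), at percentile 99.94 of 10000 lists matched on level, with 15 of the 21 well above background on replicate 1 against 17 to 21 on the others, and the kidney list next (1.41, percentile 98.53). The tables argue against the injury group, since this list differed by 0.27 between DDC injury replicates 2 and 3 and the no-injury arrays, whereas RNA from lung tissue stays a candidate explanation and a general rise of dim probes (0.86 over 6047 genes) cannot be told apart from it, the lung median exceeding that by under 3 standard errors. The brain list, with 2 of its genes in a liver list, differed the other way (-1.46 ± 0.65, percentile 0), with 17 of 19 genes well above background on replicate 1 against 10 or 11 on the others and Stmn2 at -1.83 against -8.05 to -7.15, so RNA from brain tissue may be present on replicate 1. Whether cells of either tissue would pass the sort for CD63 and the culture was not tested. Among genes well above background on the other 5 arrays, 457 lay over 2 on the log2 scale lower on replicate 1 than on every other array.

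Genes of chromosomes 15 and X lay above the other chromosomes in the DDC injury group by 0.45 ± 0.05 (1.37-fold, SE) and 0.46 ± 0.04 (1.38-fold), and those of chromosome 3 by 0.29, while those of chromosomes 4 (-0.27), 8 (-0.26), 10 (-0.21) and 12 (-0.21) lay below, each with a permutation p of 1e-04, the smallest that 10000 permutations can give. The permutations shuffled genes over chromosomes, so their p measures no variation between cultures. For chromosomes 15 and X, a few strongly changed genes are argued against, since at least 71.6% of the genes of each lay above the others' median. The scan day and the normalization are argued against as well, since in the authors' values within the second scan day the excess was 0.41 on chromosome 15 and 0.39 on X. Extra copies of both chromosomes in the injured cells' cultures remain a candidate explanation, since the excess was at least 0.39 in each of the 2 parts of both chromosomes on every DDC injury array. The excess is relative to the no-injury arrays, so this test cannot tell a gain in the DDC injury cultures from a loss in the no-injury ones. The sex of the mice and, for X, a change in its inactivation stay open and untested, Xist not being well above background on any array.

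The 3 no-injury arrays differed from each other by at most 1.69 times the noise of repeated spots, while the DDC injury arrays differed by at least 3 times. Lower noise between spots on the no-injury arrays is argued against, since the spread of their repeated spots was 0.98 times that on the DDC injury arrays. Technical noise between arrays, such as that of labelling, is not measured by repeated spots and stays open. A candidate explanation is 1 RNA or 1 culture behind the arrays, most of all replicates 1 and 3, while the series' design text speaks of 6 cell lines and replicate 2 differed from both in the chi-square test (p = 3.33e-10 and 4.87e-32), which counts no labelling noise. A biological likeness of uninjured livers stays open and untested. Of the 10 splits of the 5 samples into 3 and 2, 1, the real one, gave as many as 5225 genes and the highest other gave 6, and 10 splits are too few for a share under 0.05.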
